A study of Homo sapiens with 20 samples.

How the data were processed

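Gene expression was measured by RNA sequencing of total RNA from 5 multiple myeloma cell models (ANBL6, a bortezomib-resistant form of ANBL6 called ANBL6BR here, ARP1, RPMI8226 and U266), each with DMSO or indirubin-3'-monoxime (I3MO), with 2 libraries in each of 10 groups. Groups, doses (5 µM in ANBL6 and ANBL6BR, 10 µM in the others) and replicate numbers were taken from the labels. The deposited values are FPKM (fragments per kilobase of gene length per M fragments) for 60483 genes, and the 20 tables of single libraries held the same values as the joint table. Per the submitters' processing notes, the authors trimmed reads with Trimmomatic (0.32 and 0.36 are both named), aligned them to hg38 with STAR and used SAMtools. The counting tool and the annotation were not given in the sources used here. Symbols and gene positions were taken from GENCODE 29, in which 56753 of the gene identifiers had a symbol and 37168 had the same version.

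The files hold no counts, so fragments and gene lengths were recovered from the steps between the FPKM values, tested on 13921 single-exon genes. The total that the deposited FPKM divide by equalled the fragments on protein-coding genes, 12.11 to 20.31 M per library. The gene length in use equalled the sum of all exons over all transcripts for 100% of 966 tested multi-exon genes with the same version, and the merged exon length for 23.6%. It was longer than the merged exons by a median ratio of 1.75 over the tested genes, and over 2 times as long for 42.4%, so FPKM of genes with many transcripts are understated against other genes. In comparisons of the same gene between libraries the length acts through the filter and the 1 added to FPKM, and with merged exon lengths 16806 genes were tested, 15238 of them among the 15687. Fragments were whole to within 0.02 for 15537 of the 15687 tested genes, and a value of 0 allows up to 3 fragments, for counting error only. Fragments in exons shared between genes were apparently not counted for either gene, whatever the strand: of protein-coding genes with no shared exon 6.8% were at 0 in all libraries, against 97.2% of 179 genes covered by others on the same strand and 82.4% of 17 covered on the opposite strand. XBP1, HSPA1A and HSPA1B were listed at 0 in all libraries with 0% of their exon bases shared with another listed gene, so sharing of exons does not account for them and the reason was not found.

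Choices made before the data were examined were the comparisons, the tests, the gene lists, the rule for named genes and most alternatives. A test for counts was planned first, with limma on FPKM for the case that the files held only FPKM, and this fallback was used. Genes with FPKM of at least 1 in at least 2 libraries were tested: 15687, of which 10785 are protein-coding and 15363 have a symbol. Values were log2(FPKM + 1), fitted by limma 3.58.1 in R 4.3.3 with a mean per group over all 20 libraries and an intensity trend of the variance. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, two-sided, and a gene was called at an adjusted p under 0.05. The comparisons were I3MO against DMSO in each model, ANBL6BR against ANBL6 in DMSO, the difference of the I3MO response between ANBL6BR and ANBL6, the joint test of equal responses in the 5 models and I3MO against DMSO across the models. The last used the mean log2 value of each model and treatment, 5 against 5, with the model as a block. That comparison uses the spread between models. The others have 2 libraries per group and use a spread pooled over the 10 groups.

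Gene lists were 29 lists of pathways and complexes and 8 lists of markers of other cell types. Pathway lists were tested by camera with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 29 lists, and again with a correlation estimated from the data and by fry. Members called were counted over all tested genes and adjusted over the list alone. With an estimated correlation, the calls that held were MHC class II in ANBL6, ARP1, RPMI8226, U266, ANBL6BR against ANBL6 and the difference of the responses, replication genes in ANBL6BR, U266 and the difference, glycolysis genes in ANBL6BR, ATF4 and CHOP targets in U266, and aryl hydrocarbon receptor targets in ANBL6BR against ANBL6. The rule for named genes took the 5 largest rises and 5 largest falls per I3MO comparison and for the difference of responses, and 10 each way for ANBL6BR against ANBL6. Named genes had to be called, have a mean log2 CPM of at least 3 and have groups whose libraries did not overlap. Genes without a symbol, clone-named genes, pseudogenes, immunoglobulin and T cell receptor segments and XIST and Y-linked genes were left out of these ranks, and 1 gene that the rule took is not reported here. In each list the 2 to 4 members with the smallest p were named, and 20 genes were set to be reported whatever their values. Of the 17 of these that were tested, the values not printed did not pass.

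Alternatives were other pseudocounts and filters, limma-voom on the recovered fragments, fits on only the libraries compared, a replicate block, stricter thresholds and leaving out each library in turn. Chosen after seeing the data were median-ratio scaling of the libraries, FPKM from merged exon lengths, tests on protein-coding genes only and further checks of lists and of genes called in every model. The pipeline was tested on simulated data with 200 changed genes, 50 at each of 4 fold changes, and a dispersion of 0.02. In ANBL6 it recovered 8%, 60%, 86% and 90% of genes changed 1.5, 2, 3 and 4 times. In the difference it was 6%, 18%, 66% and 80%. Across the models, with equal folds in each, it recovered 48%, 76%, 78% and 90%, no guide where responses vary. False calls were 54 of 176 in ANBL6 (30.7%), 2 of 148 across the models and 31 of 116 in the difference (26.7%). Among genes at the level that named genes need they were 15 of 126 (11.9%), 0 of 130 and 7 of 87 (8%), and by limma-voom 14 of 153 (9.2%) in ANBL6 and 17 of 118 (14.4%) in the difference. These shares exceeded the threshold in ANBL6 and the difference. Other models, and call counts as large as theirs, were not simulated. Other software was Python 3.11.15 with NumPy 2.4.6, Numba 0.67.0, pandas 2.3.3 and matplotlib 3.10.9.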

Results

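Gene expression was measured by RNA sequencing in 5 human multiple myeloma cell models, each grown with DMSO as the vehicle or with indirubin-3'-monoxime (I3MO). Multiple myeloma is a cancer of plasma cells, and I3MO belongs to the indirubins, a family of kinase inhibitors that also bind the aryl hydrocarbon receptor. The models were the lines ANBL6, ARP1, RPMI8226 and U266 and a form of ANBL6 labelled as resistant to the proteasome inhibitor bortezomib (ANBL6BR). Each of the 10 groups held 2 libraries, 20 in all. The dose was 5 µM in ANBL6 and ANBL6BR and 10 µM in ARP1, RPMI8226 and U266, so dose and model cannot be separated between these 2 sets of models. The length of treatment was not given in the sources used here, nor whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

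The values are FPKM, and 15687 of the 60483 listed genes were tested (FPKM of at least 1 in at least 2 libraries). Library totals recovered from the FPKM steps ran from 12.11 M (mega) fragments in ANBL6 I3MO replicate 2 to 20.31 M in RPMI8226 I3MO replicate 2. Replicates correlated across genes at r = 0.962 in U266 I3MO to 0.989 in ANBL6BR I3MO and RPMI8226 I3MO, where genes are not independent replicates. In DMSO the models differed more from each other, from r = 0.685 between ANBL6 and U266 to 0.839 between ARP1 and RPMI8226. Every replicate pair differed by more than counting noise, with a chi-square per degree of freedom between 4.2 in U266 DMSO and 82.4 in ANBL6BR DMSO. Fold changes are differences of log2(FPKM + 1), I3MO minus DMSO unless stated, a scale that understates changes of low genes. They are given ± SE, a change or difference without a unit is on this log2 scale, and levels as mean ± SD with n = 2 libraries. Gene positions are on hg38.

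**Figure D1:**
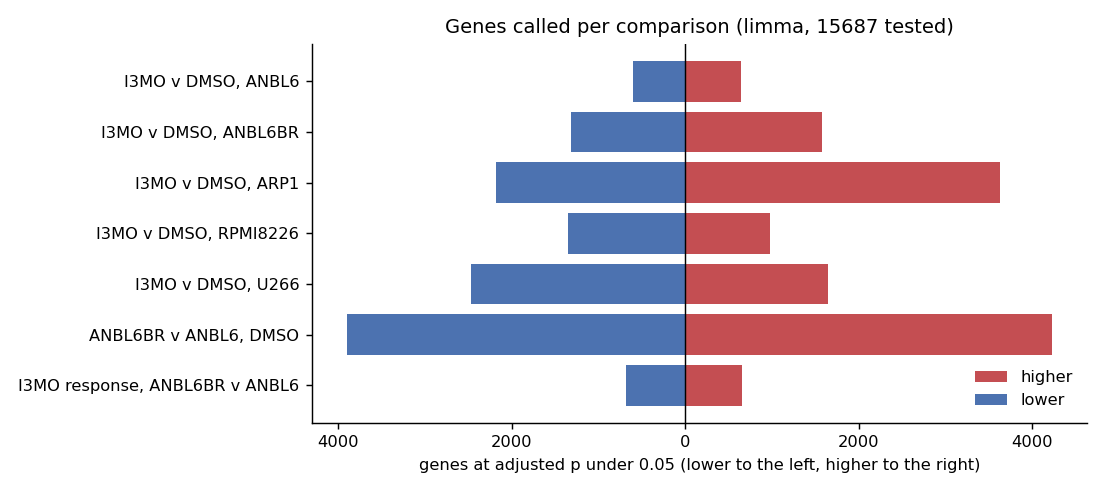
Genes called by limma (adjusted p under 0.05, of 15687 tested) in 7 comparisons, with genes lower to the left of 0 and genes higher to the right on an axis counting genes. Among the I3MO comparisons the counts run from 643 higher and 607 lower in ANBL6 to 3625 higher and 2176 lower in ARP1, and ANBL6BR against ANBL6 in DMSO has 4228 higher and 3895 lower.

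In ANBL6 with I3MO, PHGDH (ENSG00000092621.10, chromosome 1, 119648411 to 119744226), which starts serine synthesis, rose from 2.08 ± 0.375 to 14.1 ± 3.35 FPKM (SD, n = 2), a log2 fold change of 2.28 ± 0.14 (limma adjusted p = 1.64e-06). ASS1, argininosuccinate synthase (ENSG00000130707.16, chromosome 9, 130444929 to 130501274), rose from 30.4 ± 2.99 to 92.2 ± 9.63 FPKM, by 1.57 ± 0.12 (limma adjusted p = 1.54e-05). ASNS, asparagine synthetase, rose by 1.46 ± 0.13 (limma adjusted p = 4.3e-05) and the ribosomal protein gene RPS25 by 1.56 ± 0.19 (limma adjusted p = 0.000538). NUPR1, a stress-induced chromatin protein gene, rose by 1.47 ± 0.24 (limma adjusted p = 0.00351), a value that was 0.9 without ANBL6 I3MO replicate 2. SOCS3 (ENSG00000184557.4, chromosome 17, 78356778 to 78360077), a feedback inhibitor of JAK and STAT signalling, fell from 21.2 ± 9.35 to 4.96 ± 0.739 FPKM, with a log2 fold change of -1.84 ± 0.3 (limma adjusted p = 0.00362). The next falls were ANXA13 (-1.58 ± 0.06, limma adjusted p = 4.39e-08), MYBPH (-1.5 ± 0.13, limma adjusted p = 4.3e-05) and ELF3, an epithelial transcription factor gene (-1.45 ± 0.07, limma adjusted p = 3.23e-07). TXNIP, a thioredoxin-binding protein gene that responds to glucose, fell by 1.45 ± 0.26 (limma adjusted p = 0.00602), and its call was lost without ANBL6 DMSO replicate 2 (limma adjusted p = 0.0739).

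Among gene lists in ANBL6, 14 of 27 targets of ATF4 and CHOP, transcription factors of the amino acid and unfolded protein responses, rose and 0 fell. Adjusted over the list alone, 18 rose (camera adjusted p = 9.8e-12, and adjusted p = 0.0761 with an estimated correlation), with SESN2 up 1.23 and ATF4 itself up 0.74 (limma adjusted p = 0.000262 and 0.000929). Of 9 MHC class II genes, 5 fell and 4 did not pass, or 7 fell adjusted over the list alone (camera adjusted p = 1.95e-08, and adjusted p = 0.00281 with an estimated correlation). They included CIITA, the class II transactivator, at -1.02 and HLA-DRA at -1.17 (limma adjusted p = 0.000135 and 0.000692). Of 17 STAT3 and cytokine targets, 6 fell and 0 rose, or 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.23e-05, and adjusted p = 0.0761 with an estimated correlation), among them the kinase gene PIM2 at -0.85 and BCL3 at -0.76. Of 15 immediate early genes 4 fell, or 7 adjusted over the list alone (camera adjusted p = 3.23e-05, and adjusted p = 0.0761 with an estimated correlation). Only 3 of 30 ribosomal protein genes rose, with RPL32 at 0.74, but 18 did adjusted over the list alone (camera adjusted p = 7.89e-09, and adjusted p = 0.42 with an estimated correlation). Nuclear OXPHOS genes had 5 of 29 higher, or 8 adjusted over the list alone (camera adjusted p = 0.000555, and adjusted p = 0.42 with an estimated correlation). UQCRH changed by 0.69. The median of that list was 0.2, and 0.31 without ANBL6 I3MO replicate 1. ER chaperones had 2 of 23 higher, or 8 adjusted over the list alone (camera adjusted p = 0.00141, and adjusted p = 0.485 with an estimated correlation). Mitotic genes had 2 of 25 lower over all genes and adjusted over the list alone (camera adjusted p = 0.000335, and adjusted p = 0.42 with an estimated correlation), with a list median of -0.23 that was -0.35 without ANBL6 I3MO replicate 1.

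Of all genes tested in ANBL6, 1250 were called, 643 higher and 607 lower, and 118 of them changed at least 2-fold. The ANBL6 I3MO libraries held 32668 and 28419 genes above 0 against 22138 and 22710 in DMSO, at totals of 14.11 and 12.11 M fragments against 14.48 M in both. The count was 465 without DMSO replicate 1, 355 without DMSO replicate 2 and 380 without I3MO replicate 2, and 4181 genes, 80.8% of them higher, with no filter on low values. Calls near the threshold that a left-out library ended were those of interferon genes (6 of 17 higher and 2 lower, over all genes and adjusted over the list alone, camera adjusted p = 0.0169, 0.0634 without I3MO replicate 2, and adjusted p = 0.42 with an estimated correlation), p53 targets (camera adjusted p = 0.0169, 0.085 without DMSO replicate 2 and 0.0634 without I3MO replicate 2, and adjusted p = 0.42 with an estimated correlation) and mitochondrial genes (camera adjusted p = 0.0165, 0.23 without I3MO replicate 1, and adjusted p = 0.586 with an estimated correlation). The fatty acid, MHC class I and NRF2 lists, which passed at camera adjusted p = 0.0317, 0.0418 and 0.0452, were each lost without DMSO replicate 1 (0.0621, 0.143 and 0.0893; adjusted p = 0.42, 0.485 and 0.693 with an estimated correlation).

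In ANBL6BR with I3MO, SOCS3 had the largest fall among well-expressed genes, from 62.6 ± 29.1 to 6.95 ± 0.0382 FPKM (SD, n = 2), a log2 fold change of -2.92 ± 0.3 (limma adjusted p = 6.37e-05). The linker histone gene H1-10 (ENSG00000184897.5, chromosome 3, 129314771 to 129316277) went from 156 ± 51.9 to 25.6 ± 2.14 FPKM, by -2.52 ± 0.17 (limma adjusted p = 3.99e-06). H2BC11, a core histone gene whose near-identical paralogs make its reads uncertain, changed by -2.74, ID3, an inhibitor of helix-loop-helix transcription factors, by -2.72, and SPP1, which encodes osteopontin, by -2.27 (limma adjusted p = 9.64e-06, 1.92e-05 and 9.29e-05). HID1 (ENSG00000167861.14, chromosome 17, 74950743 to 74973166), a Golgi protein gene of secretory granule formation, rose from 0.757 ± 0.541 to 5.74 ± 0.594 FPKM, by 1.97 ± 0.17 (limma adjusted p = 1.97e-05). CDKN2B (ENSG00000147883.10, chromosome 9, 22002903 to 22009363), an inhibitor of cyclin-dependent kinases, rose from 15.8 ± 8.98 to 59.7 ± 3.82 FPKM, by 1.96 ± 0.24 (limma adjusted p = 0.000208). SLC17A9, a vesicular nucleotide transporter gene, rose by 1.93, PDIA3, an ER disulfide isomerase gene, by 1.91 and NUCB2 by 1.83 (limma adjusted p = 0.000115, 6.83e-05 and 5.24e-05).

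Of 25 genes of G1/S and replication, 23 fell and 2 did not pass in ANBL6BR, over all genes and adjusted over the list alone (camera adjusted p = 5.28e-25, and adjusted p = 0.0167 with an estimated correlation). MCM5 and MCM2, subunits of the replicative helicase, fell by 1.73 and 1.65 (limma adjusted p = 1.16e-07 and 1.81e-07). Of 23 replication-dependent histone genes 7 fell, or 9 adjusted over the list alone (camera adjusted p = 5.41e-05, and adjusted p = 0.236 with an estimated correlation). ER chaperones had 18 of 23 higher over all genes and adjusted over the list alone (camera adjusted p = 7.42e-13, and adjusted p = 0.156 with an estimated correlation). HYOU1 changed by 1.48 and CALR by 0.98 (limma adjusted p = 2.06e-05 for HYOU1). The DMSO libraries were split in this list too, with 1 of 23 genes higher in replicate 2 than in replicate 1 (median log2 difference -0.71), and their medians lay 0.59 (replicate 1) and 1.12 (replicate 2) below the I3MO mean. Of the ATF4 and CHOP targets 12 rose and 0 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 2.52e-05, and adjusted p = 0.236 with an estimated correlation). SESN2 changed by 1.3 and TRIB3 by 0.89. Of the glycolysis and hypoxia genes 10 of 24 fell and 1 rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 8.34e-05, and adjusted p = 0.0344 with an estimated correlation). NDRG1 changed by -1.61 (limma adjusted p = 5.45e-06). Immediate early genes had 8 of 15 lower over all genes and adjusted over the list alone (camera adjusted p = 0.000102, and adjusted p = 0.12 with an estimated correlation). DUSP1 changed by -2.15 and ZFP36 by -1.65. STAT3 and cytokine targets had 5 of 17 lower by either adjustment (camera adjusted p = 8.34e-05, and adjusted p = 0.12 with an estimated correlation), with a median of -0.28 that was -0.08 without ANBL6BR DMSO replicate 1 and -0.46 without DMSO replicate 2. Ribosomal protein genes had 13 of 30 higher, or 18 adjusted over the list alone (camera adjusted p = 2.18e-08, and adjusted p = 0.393 with an estimated correlation), and mitotic genes 4 of 25 lower (camera adjusted p = 0.000414, and adjusted p = 0.393 with an estimated correlation). CCNA2 changed by -0.92.

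Proteasome subunit and NRF2 target genes in ANBL6BR went with a difference between the DMSO libraries. Of 33 proteasome subunit genes 16 fell and 0 rose, or 24 fell adjusted over the list alone (camera adjusted p = 3.62e-10, and adjusted p = 0.393 with an estimated correlation). The list median was -0.54, and -0.84 without DMSO replicate 1 or -0.19 without DMSO replicate 2. PSMC3, a proteasome ATPase gene, fell by 0.88 (limma adjusted p = 0.00148), and its value was -0.57 without DMSO replicate 2. Of 21 NRF2 targets, genes of the oxidative stress response, 10 fell, or 12 adjusted over the list alone (camera adjusted p = 0.000163, and adjusted p = 0.449 with an estimated correlation). The NRF2 list median was -0.46, with -0.79 without DMSO replicate 1 and -0.24 without DMSO replicate 2, where the call was lost (camera adjusted p = 0.268). DMSO replicate 2 exceeded replicate 1 in all 33 proteasome genes, by a median log2 difference of 0.63, and held 825 FPKM of HMOX1, which encodes heme oxygenase, against 99, and 301 FPKM of the autophagy receptor gene SQSTM1 against 34.2. Cholesterol synthesis genes had 8 of 24 higher (camera adjusted p = 0.00278, and adjusted p = 0.544 with an estimated correlation), with medians of 0.26, 0.48 without DMSO replicate 1 and -0.02 without DMSO replicate 2 (camera adjusted p = 0.827). BCL2 family and OXPHOS genes lost their calls without DMSO replicate 1 (camera adjusted p = 0.161 and 0.121, both 0.00278 with all libraries, and adjusted p = 0.267 and 0.449 with an estimated correlation).

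In all, 2888 genes were called in ANBL6BR, 1570 higher and 1318 lower, and 358 changed at least 2-fold. The count was 1781 without I3MO replicate 1 and 1418 without I3MO replicate 2.

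In ARP1 with I3MO, CRYBB1, a lens crystallin gene (ENSG00000100122.5, chromosome 22, 26599278 to 26618088), rose from 3.36 ± 1.53 to 43.9 ± 7.99 FPKM (SD, n = 2), a log2 fold change of 3.4 ± 0.57 (limma adjusted p = 0.00063). SLC7A11, the cystine transporter gene (ENSG00000151012.12, chromosome 4, 138164097 to 138242349), rose from 0.777 ± 0.3 to 12.6 ± 4.68 FPKM, by 2.9 ± 0.37 (limma adjusted p = 0.000111). INHBE, which encodes a secreted activin subunit (ENSG00000139269.2, chromosome 12, 57452323 to 57459280), rose from 6.43 ± 0.669 to 38.3 ± 2.96 FPKM, by 2.4 ± 0.16 (limma adjusted p = 7.93e-07). LRRC58 rose by 2.43 and the sestrin gene SESN3 by 2.37 (limma adjusted p = 0.00108 and 5.52e-07). ID2 (ENSG00000115738.8, chromosome 2, 8678845 to 8684453), of the same family as ID3, fell from 20.4 ± 0.482 to 2.09 ± 0.46 FPKM, by 2.8 ± 0.21 (limma adjusted p = 2.99e-06). GPRC5D, a surface receptor gene of plasma cells, changed by -2.76 ± 0.61 (limma adjusted p = 0.00376), the linker histone gene H1-2 by -2.1 (limma adjusted p = 8.55e-06), and the transcription factor gene KLF2 by -2.08 (limma adjusted p = 0.00117).

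Of the 27 ATF4 and CHOP targets 21 rose and 0 fell in ARP1, or 25 rose adjusted over the list alone (camera adjusted p = 1.88e-09, and adjusted p = 0.142 with an estimated correlation). STC2 changed by 1.53 and ASNS by 1.61 (limma adjusted p = 2.99e-06 and 4.37e-06). Replication genes had 15 of 25 lower and 1 higher, or 15 and 3 adjusted over the list alone (camera adjusted p = 1.93e-08, and adjusted p = 0.142 with an estimated correlation). MCM5 changed by -1.47 (limma adjusted p = 1.54e-07). Of 9 MHC class II genes 7 fell over all genes and adjusted over the list alone (camera adjusted p = 8.01e-07, and adjusted p = 0.00684 with an estimated correlation). HLA-DPA1 changed by -1.3, HLA-DRA by -2.03 and CD74, the invariant chain gene, by -2.04 (limma adjusted p = 2.43e-07 for HLA-DPA1). Histone genes had 8 of 23 lower (camera adjusted p = 0.000584, and adjusted p = 0.341 with an estimated correlation). H3C10 changed by -0.97. ER chaperones had 12 higher and 1 lower, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.0174, and adjusted p = 0.684 with an estimated correlation). EDEM1 changed by 1.68 and DNAJB9 by 1.99. The median of the list, 0.42, was 0.17 after median-ratio scaling of the libraries (camera adjusted p = 0.0305). Glycolysis and hypoxia genes had 12 of 24 lower and 3 higher (camera adjusted p = 0.0174, 0.0594 with protein-coding genes only, and adjusted p = 0.142 with an estimated correlation), with VEGFA, an angiogenic growth factor gene, higher at 0.86 and ENO1 lower at -0.68.

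ARP1 had the most calls among the I3MO comparisons, 5801 genes, of which 947 changed at least 2-fold. Of the calls 62.5% were higher (3625 against 2176), and 42.8% were higher after median-ratio scaling. The count was 3681 without DMSO replicate 1 and 3509 without I3MO replicate 1, and 11 lists were called, but 7 without DMSO replicate 2. Lists lost without it were MHC class I (2 of 11 higher and 5 lower, camera adjusted p = 0.0302 with all libraries and 0.0914 without it), ribosomal proteins (called lower, with a median of -0.18, 1 of 30 higher and 4 lower, 0.0392 and 0.305), proteasome subunits (5 of 33 higher and 12 lower, 0.0452 and 0.309) and mitochondrial genes (5 of 13 higher, 0.0488 and 0.309), with adjusted p = 0.551, 0.69, 0.69 and 0.69 by camera with an estimated correlation. The last 3 were also lost without I3MO replicate 1 (camera adjusted p = 0.423, 0.195 and 0.0692). The ribosomal median was -0.41 after median-ratio scaling (camera adjusted p = 0.000702), -0.28 without DMSO replicate 1 (camera adjusted p = 0.00236) and -0.31 without I3MO replicate 2 (camera adjusted p = 0.000858). NFkB targets, with 5 of 18 lower, were lost without DMSO replicate 1 or I3MO replicate 2 (camera adjusted p = 0.0409 with all libraries, 0.0546 and 0.0608, and adjusted p = 0.341 with an estimated correlation).

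In RPMI8226 with I3MO, PHGDH rose from 12 ± 0.73 to 48.0 ± 0.0136 FPKM (SD, n = 2), a log2 fold change of 1.92 ± 0.14 (limma adjusted p = 3.42e-06). MANF (ENSG00000145050.14, chromosome 3, 51385047 to 51389397), which encodes a secreted ER stress protein, rose from 30.3 ± 0.754 to 93.3 ± 2.25 FPKM, by 1.59 ± 0.27 (limma adjusted p = 0.00163). SYTL1, a vesicle trafficking gene, rose by 1.63, HID1 by 1.51 and PARM1 by 1.51 (limma adjusted p = 1.08e-05, 9.14e-05 and 2.55e-05). ERVV-2 (ENSG00000268964.1, chromosome 19, 53044738 to 53051076) and its neighbour ERVV-1, retroviral envelope genes alike enough that their reads are uncertain, changed by -2.7 ± 0.1 and -2.17 ± 0.14 (limma adjusted p = 5.07e-08 and 1.04e-06). UBALD2 (ENSG00000185262.8, chromosome 17, 76265202 to 76271299) fell from 69.7 ± 1.92 to 12.2 ± 1.5 FPKM, by 2.43 ± 0.13 (limma adjusted p = 5.57e-07). BBC3, a pro-apoptotic p53 target, fell from 7.1 ± 1.71 to 0.555 ± 0.0111 FPKM, by 2.37 ± 0.19, and METTL7A by 2.14 ± 0.26 (limma adjusted p = 6.4e-06 and 0.000147).

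Of the ATF4 and CHOP targets 14 of 27 rose over all genes and adjusted over the list alone (camera adjusted p = 5.9e-11, and adjusted p = 0.107 with an estimated correlation). SHMT2, a mitochondrial serine enzyme gene, changed by 1.03 and SLC3A2 by 1.28. ER chaperones had 11 of 23 higher, or 15 adjusted over the list alone (camera adjusted p = 5.9e-11, and adjusted p = 0.195 with an estimated correlation). HYOU1 changed by 1.07 and CRELD2 by 1.43. Mitotic genes had 9 of 25 lower, or 17 adjusted over the list alone (camera adjusted p = 5.62e-08, and adjusted p = 0.195 with an estimated correlation). KIF20A changed by -1.18 (limma adjusted p = 2.31e-05). Of 21 p53 targets 9 fell by either adjustment (camera adjusted p = 1.16e-05, and adjusted p = 0.126 with an estimated correlation). DDB2, a DNA repair gene, changed by -0.77. Interferon genes had 9 of 17 lower, or 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.73e-05, and adjusted p = 0.195 with an estimated correlation). STAT2 changed by -0.72. MHC class II had 5 of 9 lower by either adjustment (camera adjusted p = 8.07e-05, and adjusted p = 0.0345 with an estimated correlation). HLA-DPA1 changed by -1.01 and HLA-DRA by -0.93. NRF2 targets had 4 of 21 higher, or 6 adjusted over the list alone (camera adjusted p = 0.00042, and adjusted p = 0.567 with an estimated correlation). NQO1 changed by 0.77. Heat shock genes had 4 of 17 higher and 1 lower, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00115, and adjusted p = 0.4 with an estimated correlation), with the collagen chaperone gene SERPINH1 at 1.42 (limma adjusted p = 1.04e-06) and BAG3 at 1.29. Replication genes had 7 of 25 lower and 1 higher, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00127, and adjusted p = 0.4 with an estimated correlation), and MCM5 changed by -0.66 but CCNE1, cyclin E, by 0.68.

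RPMI8226 had 2323 calls, 971 higher and 1352 lower, and 261 changed at least 2-fold. The count was 1427 and 1379 without DMSO replicates 1 and 2, and 1144 and 1362 without I3MO replicates 1 and 2. Mitochondrial genes (0 of 13 past the test singly, camera adjusted p = 0.014, and adjusted p = 0.713 with an estimated correlation) lost their call without DMSO replicate 2 (camera adjusted p = 0.193). Histone genes had 3 of 23 lower, or 5 adjusted over the list alone (camera adjusted p = 0.00263, and adjusted p = 0.4 with an estimated correlation). H3C10 changed by -0.8.

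In U266 with I3MO, EGR1 (ENSG00000120738.7, chromosome 5, 138465490 to 138469315), an immediate early transcription factor gene, fell from 174 ± 6.96 to 3.75 ± 0.732 FPKM (SD, n = 2), a log2 fold change of -5.21 ± 0.68 (limma adjusted p = 0.000122). E2F2 (ENSG00000007968.6, chromosome 1, 23506430 to 23531220), a transcription factor gene of S phase entry, fell from 64.9 ± 2.98 to 8.46 ± 0.693 FPKM, by 2.8 ± 0.09 (limma adjusted p = 2.39e-09). RRM2, which encodes a ribonucleotide reductase subunit, changed by -2.86, UBALD2 by -2.59 and the sialyltransferase gene ST6GAL1 by -2.53 (limma adjusted p = 1.09e-05, 6.77e-08 and 1.26e-05). BHLHA15 (ENSG00000180535.3, chromosome 7, 98211427 to 98212979), a transcription factor gene of secretory cells, rose from 4.07 ± 0.476 to 35.6 ± 0.83 FPKM, by 2.85 ± 0.34 (limma adjusted p = 6.34e-05). SAT1, a polyamine-degrading enzyme gene, rose by 2.82, INHBE by 2.75 and SYTL3 by 2.62 (limma adjusted p = 9.36e-05, 1.42e-07 and 2.78e-09). HMOX1 (ENSG00000100292.15, chromosome 22, 35380361 to 35394214) rose from 64.7 ± 0.803 to 343 ± 0.00924 FPKM, by 2.39 ± 0.65 (limma adjusted p = 0.0163), where the SE is shared with ANBL6BR DMSO. That call was lost with either DMSO library (limma adjusted p = 0.0733 and 0.0711 without replicates 1 and 2) or either I3MO library of U266 left out (limma adjusted p = 0.057 and 0.0592).

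All 25 replication genes fell in U266 over all genes and adjusted over the list alone (camera adjusted p = 1.03e-22, and adjusted p = 0.0083 with an estimated correlation). MCM5 changed by -1.8 and CDC45 by -1.79 (limma adjusted p = 9.69e-09 for MCM5). Mitotic genes had 21 of 25 lower, or 22 adjusted over the list alone (camera adjusted p = 7.5e-11, and adjusted p = 0.0876 with an estimated correlation). CCNA2, cyclin A, changed by -1.96 (limma adjusted p = 1.61e-07). Of the 27 ATF4 and CHOP targets 25 rose, or 26 adjusted over the list alone (camera adjusted p = 2.09e-23, and adjusted p = 0.0083 with an estimated correlation). STC2 changed by 2.36 and SHMT2 by 1.89 (limma adjusted p = 6.3e-08 for STC2). ER chaperones had 18 of 23 higher and 1 lower, or 19 and 1 adjusted over the list alone (camera adjusted p = 4.73e-10, and adjusted p = 0.156 with an estimated correlation). HSPA5, the chaperone BiP, changed by 1.7. All 9 MHC class II genes fell (camera adjusted p = 1.18e-07, and adjusted p = 0.00481 with an estimated correlation). HLA-DMA changed by -0.85. Interferon genes had 11 of 17 lower, or 14 adjusted over the list alone (camera adjusted p = 1.83e-07, and adjusted p = 0.0876 with an estimated correlation). MX1, an antiviral GTPase gene, changed by -2.3 and IRF7 by -1.37 (limma adjusted p = 1.06e-09 for MX1). STAT3 and cytokine targets had 10 of 17 lower and 1 higher, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.156 with an estimated correlation). PIM2 changed by -1.77 and IL6 by -0.62. WNT targets had 3 of 7 lower by either adjustment (camera adjusted p = 0.0169, and adjusted p = 0.156 with an estimated correlation): CCND1, cyclin D, at -2.46, the WNT antagonist gene DKK1 at -0.8 and RNF43 at -0.32.

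In U266, 4117 genes were called, 1645 higher and 2472 lower, and 766 changed at least 2-fold. The calls of p53 targets, MHC class I and mitochondrial genes were lost without DMSO replicate 2 (camera adjusted p = 0.0348, 0.0243 and 0.0203 with all libraries and 0.0536 for each without it), and that of glycolysis genes without DMSO replicate 2 or I3MO replicate 1 (camera adjusted p = 0.0348 with all libraries, 0.0766 and 0.204). The p53 and MHC class I calls were also lost without I3MO replicate 2 (camera adjusted p = 0.0753 and 0.0557) and the mitochondrial call without I3MO replicate 1 (camera adjusted p = 0.0641). With an estimated correlation, p53, MHC class I, mitochondrial and glycolysis genes had camera adjusted p = 0.452, 0.525, 0.685 and 0.156.

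**Figure D2:**
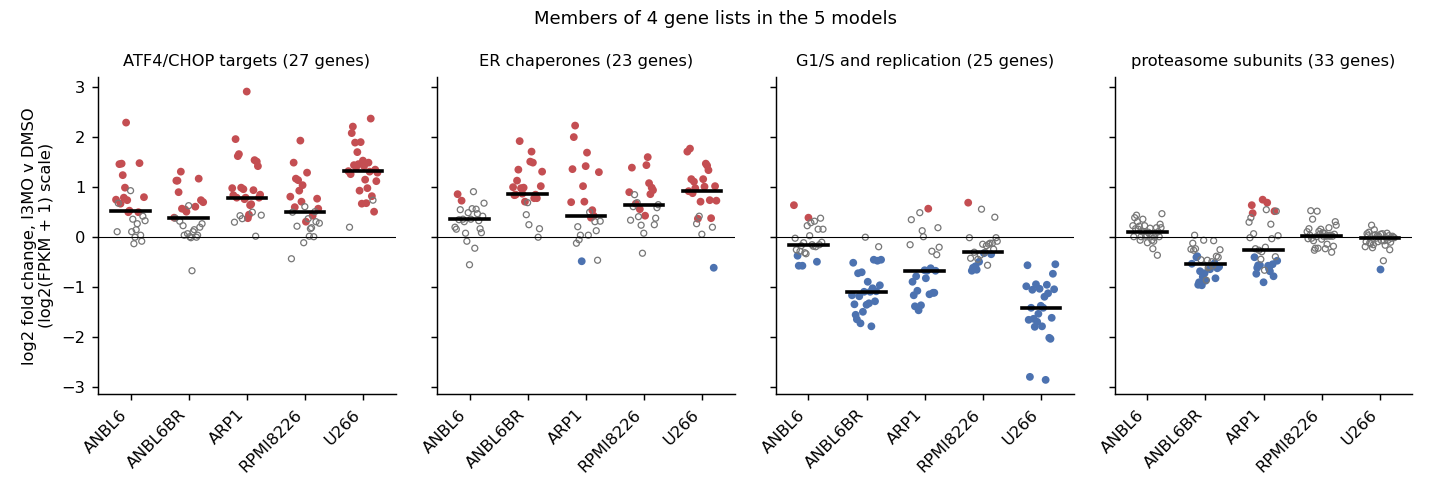
Log2 fold changes of I3MO against DMSO (log2(FPKM + 1) scale) for each member of 4 gene lists in the 5 models, with filled points for genes called by limma, open points for the rest and a bar at the list median. Medians of ATF4 and CHOP targets run from 0.37 in ANBL6BR to 1.31 in U266, and those of replication genes from -0.16 in ANBL6 to -1.42 in U266.

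The comparison across models asked which responses were shared, with each model counted as 1 replicate. By limma it called 0 genes at an adjusted p under 0.05, while 2651 had an unadjusted p under 0.05. By limma-voom it called 308 genes, and limma called 65 when only protein-coding genes were tested and 3638 when all 20 libraries entered with the model as a block. Counting calls within the models, 46 genes were higher and 51 lower in every model. The 5 sets of calls share a spread pooled over the 10 groups, so they are not independent of each other. The sum of 97 was 0 with only the libraries compared in each fit, 1 with a fold change of at least 2 required, and 50, 36 and 43 without ANBL6 DMSO replicate 1, ANBL6 DMSO replicate 2 and ANBL6 I3MO replicate 2. With ANBL6 set aside, 124 genes were higher and 141 lower in each of the other 4 models. The genes named next follow a rule chosen after the values were seen, the 10 largest mean changes each way among the shared calls with a mean log2 CPM of at least 3. Among the rises INHBE ranged from 0.9 in ANBL6BR to 2.75 in U266, ASS1 from 0.48 to 2.37, CHAC1, a glutathione-degrading enzyme gene, from 1.12 to 2.07 and CTH, which makes cysteine, from 0.58 to 2.33. DNAJB9, an ER co-chaperone gene whose ANBL6 call was lost with any ANBL6 library left out (limma adjusted p up to 0.192), ranged from 0.84 to 1.99. KRCC1 ranged from 0.73 to 1.71, HID1 from 0.58 to 1.97, ADM2, which encodes a peptide hormone, from 0.71 to 1.53, ARFGAP3, a Golgi trafficking gene, from 0.58 to 1.39 and TRIB3, a pseudokinase gene of the ATF4 response, from 0.59 to 2.2. H1-10 had the largest mean fall, between -2.52 and -0.92, followed by UBALD2 between -2.59 and -0.98, E2F2 between -2.8 and -0.38 and APOBEC3B, a cytidine deaminase gene, between -1.67 and -0.67. MCM5 was between -1.8 and -0.58, PBXIP1 between -1.57 and -0.72, BMF, a pro-apoptotic BCL2 family gene, between -1.55 and -0.74, PIM2 between -1.77 and -0.32, MCM2 between -1.65 and -0.58 and TMEM238 between -1.35 and -0.65. In the test across models CHAC1 and H1-10 had log2 fold changes of 1.61 ± 0.15 and -1.66 ± 0.23, each with limma adjusted p = 0.0918.

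**Figure D3:**
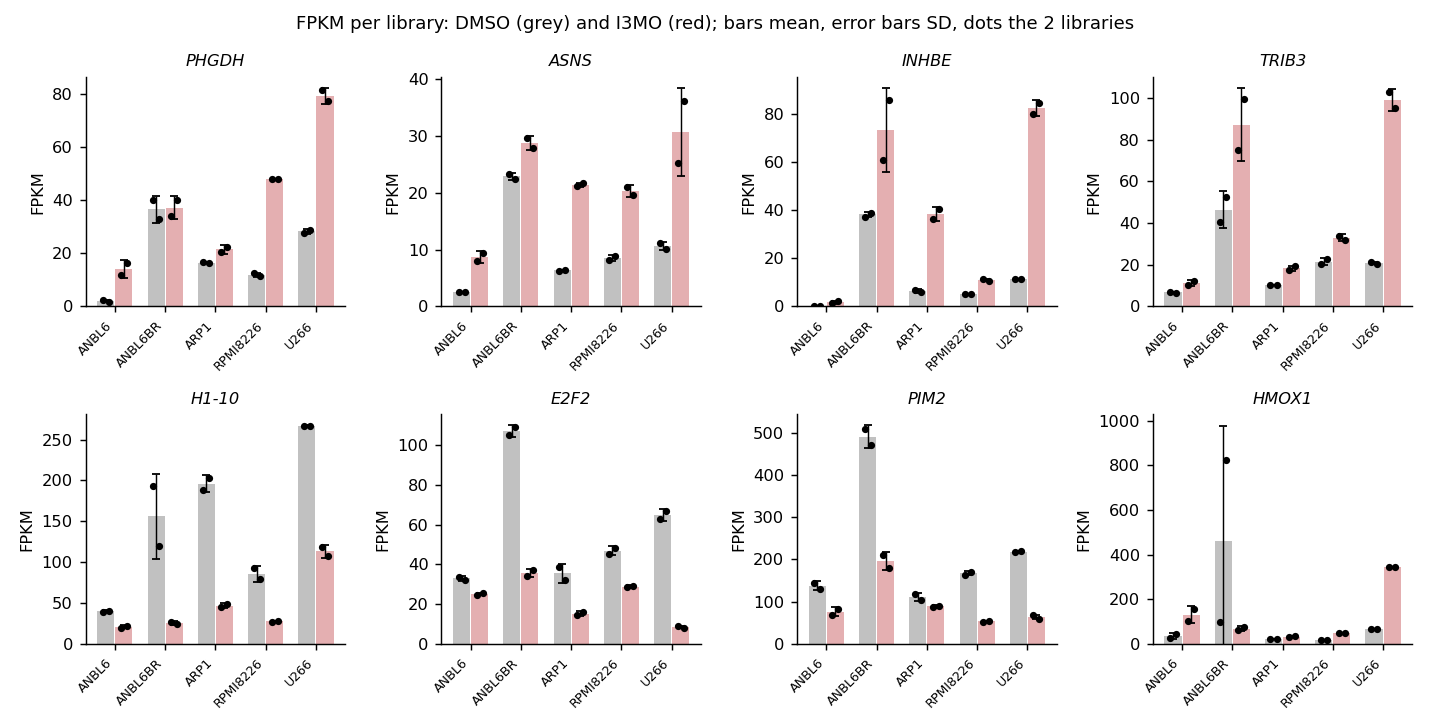
FPKM of 8 genes in the 5 models, with grey bars for the DMSO mean, red bars for the I3MO mean, error bars for the SD and dots for the 2 libraries. H1-10, E2F2 and PIM2 are lower with I3MO in each model, and HMOX1 in ANBL6BR DMSO is split between 99 and 825 FPKM.

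At the level of lists, 3 were called higher and 12 lower across the models, and 0 of these calls held with an estimated correlation. No member passed limma over all genes, so the counts that follow are adjusted over the list alone. ATF4 and CHOP targets had 19 of 27 higher (camera adjusted p = 2.99e-16, and adjusted p = 0.333 with an estimated correlation) and ER chaperones 18 of 23 (camera adjusted p = 5.42e-13, and adjusted p = 0.271 with an estimated correlation). Replication genes had 15 of 25 lower (camera adjusted p = 6.65e-12, and adjusted p = 0.36 with an estimated correlation), MHC class II genes 7 of 9 (camera adjusted p = 4.38e-06, and adjusted p = 0.354 with an estimated correlation) and STAT3 and cytokine targets 7 of 17 (camera adjusted p = 0.00031, and adjusted p = 0.333 with an estimated correlation). Ribosomal protein genes had 0 of 30 past limma adjusted over the list alone and a median of 0.19 (camera adjusted p = 9.78e-06, and adjusted p = 0.547 with an estimated correlation), while in ARP1 alone of the models the list was called lower (-0.18). Of the lists called lower, plasma cell identity genes lost their call without ANBL6BR DMSO replicate 1 (camera adjusted p = 0.00509 with all libraries and 0.0914 without it), and proteasome subunits without ANBL6BR DMSO replicate 2 or U266 I3MO replicate 1 (camera adjusted p = 0.0116 with all libraries, 0.176 and 0.0567). With an estimated correlation these had camera adjusted p = 0.36 and 0.826.

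Fold changes of 2 models correlated across genes at r = 0.06 for ANBL6 and ARP1 up to 0.34 for ANBL6BR and U266, and at 0.19 for ANBL6 and ANBL6BR. Genes are not independent replicates, and no control library was shared between models. ANBL6 and ANBL6BR shared 177 genes called higher and 162 called lower, in fits with the same pooled spread. The joint limma test of equal responses in the 5 models called 6980 of 15687 genes (8480 at an unadjusted p under 0.05), with dose and model confounded.

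The comparison of ANBL6BR with ANBL6 in DMSO asked how the bortezomib-resistant cells differed without I3MO. ACTL8, an actin-like gene of testis (ENSG00000117148.7, chromosome 1, 17755313 to 17827063), stood at 243 ± 20.6 FPKM in ANBL6 and 0.392 ± 0.192 in ANBL6BR (SD, n = 2), a log2 difference of -7.46 ± 0.1 (limma adjusted p = 3.18e-14). HSPB1, a small heat shock protein gene (ENSG00000106211.8, chromosome 7, 76302544 to 76304295), stood at 172 ± 3.62 FPKM in ANBL6 and 0.0481 ± 0.0342 in ANBL6BR, a difference of -7.37 ± 0.1 (limma adjusted p = 4.77e-14). AFAP1-AS1 differed by -7.22, but it is an antisense gene, and if strand was not used in counting its reads are uncertain. CD74 differed by -4.92 and CD70, a tumour necrosis factor family ligand gene, by -4.53 (limma adjusted p = 2.09e-11 and 8.73e-11), LRRC14B by -6.01, S100A4 by -4.61, MGAT3 by -4.4, IL32 by -4.39 and PNPLA7 by -4.32. CD180, a Toll-like receptor homologue gene of B cells (ENSG00000134061.5, chromosome 5, 67179613 to 67196799), stood at 87.1 ± 35.7 FPKM in ANBL6BR and 0.0644 ± 0.00827 in ANBL6, a difference of 6.31 ± 0.18 (limma adjusted p = 1.94e-11). CKAP4, an ER membrane protein gene, differed by 5.64, the galectin gene LGALS3 by 5.45, H1-2 by 5.16 (882 ± 46 against 23.6 ± 0.299 FPKM), TAS1R3 by 5.15, INHBE by 5.13 and BMP6, a growth factor gene, by 4.36 (limma adjusted p = 8.09e-11 for CKAP4 and 1.01e-12 for LGALS3). AASS and PARM1 were higher by 4.56 and 4.53, and SSX1, whose reads may be shared within its family, by 4.47.

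ATF4 and CHOP targets were higher in ANBL6BR for 23 of 27 genes and lower for 3, over all genes and adjusted over the list alone (camera adjusted p = 3.57e-07, and adjusted p = 0.209 with an estimated correlation). PHGDH differed by 3.61 and ASNS by 2.77 but STC2 by -2.96. MHC class II had 8 of 9 lower and 1 higher (camera adjusted p = 1.02e-05, and adjusted p = 0.0124 with an estimated correlation). HLA-DRA differed by -5.84 (limma adjusted p = 5.44e-12). All 5 tested targets of the aryl hydrocarbon receptor were lower (camera adjusted p = 0.000508, and adjusted p = 0.0299 with an estimated correlation). NQO1 differed by -2.19 and CYP1A1 by -1.49. Of the 33 proteasome subunits 22 were higher and 2 lower (camera adjusted p = 0.000671, and adjusted p = 0.609 with an estimated correlation). PSMD8 differed by 2.3 and the bortezomib target PSMB5 by 1.38. Their median was 0.64, and 0.34 without ANBL6BR DMSO replicate 2, the library that also stood apart in proteasome, HMOX1 and SQSTM1 levels. Ribosome biogenesis genes had 16 of 23 lower and 1 higher, or 17 and 1 adjusted over the list alone (camera adjusted p = 0.0019, and adjusted p = 0.599 with an estimated correlation). MYC differed by -3.95. OXPHOS genes had 18 of 29 lower and 3 higher, or 19 and 3 adjusted over the list alone (camera adjusted p = 0.00201, and adjusted p = 0.609 with an estimated correlation), and ribosomal protein genes 18 of 30 lower and 3 higher, or 21 and 3 adjusted over the list alone (camera adjusted p = 0.000731, and adjusted p = 0.609 with an estimated correlation). Heat shock genes had 10 of 17 lower and 1 higher, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00634, and adjusted p = 0.609 with an estimated correlation). BAG3 differed by -4.17. The median of the list, -0.61, was -0.22 without ANBL6BR DMSO replicate 1, where the call was lost (camera adjusted p = 0.0687), and -0.96 without replicate 2. Replication genes had 15 of 25 higher and 5 lower, or 16 and 5 adjusted over the list alone (camera adjusted p = 0.0165, and adjusted p = 0.609 with an estimated correlation). E2F2 differed by 1.67.

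In total 8123 of 15687 genes differed between ANBL6BR and ANBL6, 4228 higher and 3895 lower, and 2931 of them at least 2-fold. The most abundant light chain variable gene also differed: IGLV2-14 held 99.9% of IGLV2 fragments in each ANBL6BR library and at most 4.0% in ANBL6.

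**Figure D4:**
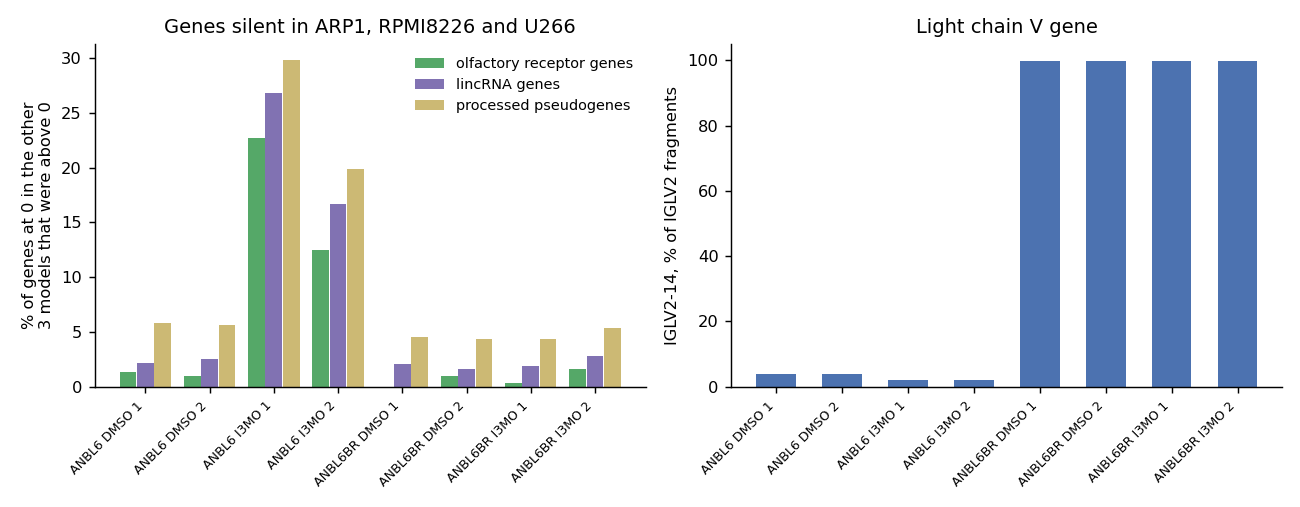
Left, percent of olfactory receptor, lincRNA and processed pseudogene genes at 0 in ARP1, RPMI8226 and U266 that were above 0 in each ANBL6 and ANBL6BR library; right, percent of IGLV2 fragments on IGLV2-14 in the same libraries. The ANBL6 I3MO libraries reach 22.7% and 12.5% of olfactory receptor genes against at most 1.6% in the other 6, and IGLV2-14 separates ANBL6BR at 99.9% from ANBL6 at 4.0% or less.

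Whether the resistant cells responded differently was tested as the I3MO response of ANBL6BR minus that of ANBL6, both at 5 µM. CDKN2B differed by 2.06 ± 0.34 (limma adjusted p = 0.00412). It rose by 1.96 in ANBL6BR and had a log2 fold change of -0.1 in ANBL6, where it stood at 0.32 FPKM in DMSO. HYOU1 (ENSG00000149428.17, chromosome 11, 119044189 to 119057202), an ER chaperone gene, differed by 1.71 ± 0.18 (limma adjusted p = 0.000268), with 1.48 in ANBL6BR against -0.23 in ANBL6. SLC17A9 differed by 1.86 ± 0.31 and CYTH4 by 1.61 ± 0.29 (limma adjusted p = 0.00412 and 0.00627). H1-2 (ENSG00000187837.3, chromosome 6, 26055787 to 26056428) fell in ANBL6BR from 882 to 203 FPKM and rose in ANBL6 from 23.6 to 45.3, a difference of -2.97 ± 0.26 (limma adjusted p = 6.41e-05). H2BC12 likewise rose by 1.27 in ANBL6 and changed by -1.02 in ANBL6BR, a difference of -2.3 ± 0.3, and H2BC11 differed by -2.68 ± 0.3 (limma adjusted p = 0.00106 and 0.000369), both with reads that paralogs make uncertain. ID3 differed by -2.3 ± 0.33 (limma adjusted p = 0.00191). TXNIP differed by 1.72 ± 0.37 (limma adjusted p = 0.0157), a call lost without ANBL6 DMSO replicate 2 or ANBL6BR I3MO replicate 1 (limma adjusted p = 0.0654 and 0.056). HMOX1 differed by -3.96 ± 0.92 (limma adjusted p = 0.0215), but by -2.44 without ANBL6BR DMSO replicate 2, and its call was lost without ANBL6 DMSO replicate 1, ANBL6 I3MO replicate 2 or either ANBL6BR I3MO library (limma adjusted p between 0.0609 and 0.0872).

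The response of replication genes was lower in ANBL6BR than in ANBL6 for 17 of 25 genes, or 23 adjusted over the list alone (camera adjusted p = 1.8e-20, and adjusted p = 0.0173 with an estimated correlation), with a difference of -1.74 for the licensing factor gene CDT1 and -1.8 for CCNE1. MHC class II genes differed upward for 4 of 9, or 6 adjusted over the list alone (camera adjusted p = 2.29e-05, and adjusted p = 0.0173 with an estimated correlation). CIITA differed by 1.03. The median of the list, 0.59, was 0.38 without ANBL6BR I3MO replicate 2. This difference restates the fall in ANBL6: in ANBL6BR DMSO the tested genes other than CD74 (13.2 FPKM) stood at 0.219 FPKM at most, so they had next to nothing to lose, and the median change with I3MO there was 0. Proteasome subunits had 5 of 33 lower, or 15 adjusted over the list alone (camera adjusted p = 4.94e-10, and adjusted p = 0.361 with an estimated correlation). Their median of -0.6 was -0.94 without ANBL6BR DMSO replicate 1 and -0.33 without replicate 2, which stood above replicate 1 in all 33 of these genes. NRF2 targets had 6 of 21 lower and 1 higher, or 11 and 1 adjusted over the list alone (camera adjusted p = 7.66e-06, and adjusted p = 0.361 with an estimated correlation), with a median of -0.71 that was -1.12 and -0.32 without those libraries. ER chaperones had 5 of 23 higher, or 6 adjusted over the list alone (camera adjusted p = 6.35e-06, and adjusted p = 0.361 with an estimated correlation), with a median of 0.64, or 0.24 without ANBL6BR DMSO replicate 2. Histone genes had 9 of 23 lower (camera adjusted p = 0.000153, and adjusted p = 0.361 with an estimated correlation), with a median of -0.53, or -0.15 without ANBL6 DMSO replicate 1 and -0.27 without ANBL6 I3MO replicate 2. NDRG1 at -1.38 stood out among glycolysis and hypoxia genes, of which 9 of 24 differed downward and 1 upward, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00192, and adjusted p = 0.0809 with an estimated correlation). In all 1328 genes differed, 649 upward and 679 downward, and the count was 573, 614 and 589 without ANBL6 DMSO replicates 1 and 2 and I3MO replicate 2. Without ANBL6BR DMSO replicate 1 it was 2201, without I3MO replicates 1 and 2 of ANBL6BR 743 and 555, and by limma-voom 871.

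Genes chosen for report whatever their values included targets of the aryl hydrocarbon receptor. CYP1A1 (ENSG00000140465.12, chromosome 15, 74719542 to 74725610), a monooxygenase gene that this receptor induces, rose in ARP1 from 0.308 ± 0.0265 to 1.22 ± 0.00107 FPKM (SD, n = 2), by 0.76 ± 0.08 (limma adjusted p = 1.76e-05). It changed by -0.4 in ANBL6 and in RPMI8226 (limma adjusted p = 0.00786 and 0.00348), the ANBL6 call being lost without DMSO replicate 1 (limma adjusted p = 0.0805), and did not pass in ANBL6BR or U266 (limma adjusted p = 1 and 0.981). AHRR, the receptor's repressor gene, rose in ANBL6BR by 0.5 (limma adjusted p = 0.00228), and its change of -0.35 in ANBL6 (limma adjusted p = 0.0329) was lost with any ANBL6 library left out (limma adjusted p up to 0.229). TIPARP rose in ARP1 by 0.8 (limma adjusted p = 0.000497). CYP1B1 was not tested, and stood at 0.0968 and 0.15 FPKM in ARP1 DMSO (18 and 30 fragments) and 1.25 and 0.926 in ARP1 I3MO (207 and 170 fragments), with at most 8 fragments in any other library. The receptor's target list passed in ANBL6, with 3 of 5 genes lower (camera adjusted p = 0.0244, 0.0773 without I3MO replicate 1, and adjusted p = 0.148 with an estimated correlation), but not in ARP1, with 2 higher, or 3 adjusted over the list alone (camera adjusted p = 0.103).

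The kinase gene PIM2 (ENSG00000102096.9, chromosome X, 48913182 to 48919024) fell in each model, from 218 ± 2.17 to 63.3 ± 5.5 FPKM in U266 (SD, n = 2; -1.77, limma adjusted p = 3.35e-07), by 1.63 in RPMI8226, 1.32 in ANBL6BR and 0.85 in ANBL6. Its fall of 0.32 in ARP1 (limma adjusted p = 0.0411) was lost without DMSO replicate 1 or either I3MO library (limma adjusted p = 0.25, 0.184 and 0.0805). PIM1 fell by 2.11 in U266, 1.99 in ANBL6BR, 1.07 in RPMI8226 and 0.98 in ARP1 and was -0.59 in ANBL6 (limma adjusted p = 1.26e-05, 7.01e-05, 0.00403, 0.00291 and 0.107), and PIM3 fell in ANBL6BR by 1.26 (limma adjusted p = 0.000365). The response of PIM1 differed between ANBL6BR and ANBL6 by -1.4 ± 0.29 (limma adjusted p = 0.0144), a call lost without ANBL6 DMSO replicate 1, ANBL6 I3MO replicate 2 or ANBL6BR I3MO replicate 2 (limma adjusted p = 0.0576, 0.0636 and 0.0653). ATF4 rose by 0.74, 0.97, 0.8 and 1.31 in ANBL6, ARP1, RPMI8226 and U266, and by 0.38 in ANBL6BR (limma adjusted p = 0.0183), a call lost without DMSO replicate 2 or either I3MO library of ANBL6BR (limma adjusted p = 0.109, 0.064 and 0.115). DDIT3, which encodes CHOP, rose by 1.25 in U266 and 1.12 in ANBL6BR (limma adjusted p = 0.00152 and 0.00518), the latter 0.66 without ANBL6BR I3MO replicate 2. MYC and the plasma cell factor gene IRF4 passed in no I3MO comparison, with limma adjusted p between 0.0554 and 0.819 for MYC. Mean MYC was still lower with I3MO in ANBL6 (99.7 to 65.9 FPKM), ARP1 (36.8 to 22.9), RPMI8226 (111 to 49.5) and U266 (0.686 to 0.239). In ANBL6BR it was 6.74 and 6.68. The pooled spread takes in the ANBL6BR DMSO libraries, which held 10.9 and 2.55 FPKM of MYC and 265 and 93.2 of IRF4. No call is therefore no sign of an unchanged level.

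TXNIP fell in RPMI8226 by 1.5 and in U266 by 1.37 (limma adjusted p = 0.00203 and 0.00182). CDKN1A, a p53-induced cell cycle inhibitor gene, rose in ARP1 by 1.65 (limma adjusted p = 0.000354). Its changes of -0.82 in RPMI8226 and -0.89 in U266 (limma adjusted p = 0.0469 and 0.0199) were lost with any RPMI8226 library left out (limma adjusted p up to 0.204), and without U266 DMSO replicate 1, DMSO replicate 2 or I3MO replicate 2 (limma adjusted p = 0.0823, 0.0829 and 0.0966). MCL1, an anti-apoptotic gene, fell in U266 by 1.24 and the deubiquitinase gene USP7 by 0.59 (limma adjusted p = 4.1e-05 and 0.000253), and the proteasome activator gene PSME3 fell in ARP1 by 0.51 (limma adjusted p = 0.00464), a log2 value that was -0.29 without DMSO replicate 1. HMOX1 changed in ANBL6BR by -2.07 ± 0.65 (limma adjusted p = 0.044), a value of -3.6 without DMSO replicate 1, -0.55 without DMSO replicate 2 (limma adjusted p = 0.232), and not called with either I3MO library left out (limma adjusted p = 0.186 and 0.129). Its log2 fold changes of 1.89, 0.55 and 1.36 in ANBL6, ARP1 and RPMI8226 did not pass (limma adjusted p = 0.0985, 0.597 and 0.212). PSMB5 passed in no I3MO comparison. In DMSO, PIM1 and PIM2 were higher in ANBL6BR than in ANBL6 by 2.93 and 1.83, IRF4 by 2.75 and MCL1 by 1.18 (limma adjusted p = 1.03e-07, 2.21e-08, 1.21e-05 and 1.37e-05). HMOX1 differed by 3.05, or 1.52 without ANBL6BR DMSO replicate 2, DDIT3 by 1.04 and ATF4 by 0.5 (limma adjusted p = 0.00154, 0.00209 and 0.000812). TIPARP differed by -1.09, PSME3 by -0.86, USP7 by -0.77 and AHRR by -0.69 (limma adjusted p = 1.2e-05, 4.61e-05, 7.1e-06 and 2.87e-05). CDKN1A at 0.81, TXNIP at -0.7 and PIM3 at 0.53 (limma adjusted p = 0.0163, 0.0391 and 0.0177) each lost the call with either of 2 single libraries left out (limma adjusted p up to 0.233, 0.337 and 0.221). XBP1, HSPA1A and HSPA1B were listed at 0 in all 20 libraries for a reason not found, so absence of expression cannot be read from it. CRYAB was at most 0.0287 FPKM, and ABCB1, a drug efflux pump gene, was at most 0.185 FPKM (56 fragments, ARP1 I3MO replicate 1).

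Of the pathway lists, those of proteasome activators, autophagy and lysosome genes and drug transporters passed in no comparison. Where a list's median, mean and test differed in sign, the list had not passed: histones in ANBL6BR against ANBL6, for example, had a median of -0.1 and a mean of 0.56 (camera adjusted p = 0.561). Markers of other cell types were rarely expressed: 5 B cell markers were tested, 2 each of myeloid, stromal and epithelial cells, and 1 each of T, NK, erythroid and endothelial cells. In any I3MO comparison at most 1 marker of a type rose and at most 1 fell.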

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

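All tests of explanations here were chosen after the results were seen, while the tests of a difference in response were planned. The I3MO response differed between ANBL6BR and ANBL6 in 1328 genes and between the 5 models in 6980 genes, each by limma's test of the difference itself. Dose and model are confounded in the joint test. The single genes that this test singled out between ANBL6BR and ANBL6 were CDKN2B (2.06), SLC17A9 (1.86), TXNIP (1.72), HYOU1 (1.71) and CYTH4 (1.61) with a higher response in ANBL6BR, and HMOX1 (-3.96), H1-2 (-2.97), H2BC11 (-2.68), H2BC12 (-2.3) and ID3 (-2.3) with a lower response. TXNIP lost its call without ANBL6 DMSO replicate 2 or ANBL6BR I3MO replicate 1 (1.43 and 1.36), and HMOX1 was -2.44 without ANBL6BR DMSO replicate 2. HMOX1 also lost its call without ANBL6 DMSO replicate 1 (-3.6), ANBL6 I3MO replicate 2 (-3.66), ANBL6BR I3MO replicate 1 (-3.79) and ANBL6BR I3MO replicate 2 (-4.13). Of genes always reported, AHRR differed by 0.86, PIM1 by -1.4 and CYP1A1 by 0.38. PIM1 lost its call without ANBL6 DMSO replicate 1 (-1.34), ANBL6 I3MO replicate 2 (-1.26) or ANBL6BR I3MO replicate 2 (-1.2). CYP1A1 lost its call with any ANBL6 or ANBL6BR library left out except ANBL6 I3MO replicate 2 (limma adjusted p up to 0.171), and by limma-voom its direction turned (-0.58, limma-voom adjusted p = 0.697).

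The lists whose response differed between ANBL6BR and ANBL6 had these median differences: replication genes -0.94, NRF2 targets -0.71, proteasome subunits -0.6, histones -0.53, OXPHOS genes -0.32, interferon genes -0.32, BCL2 family genes -0.29, glycolysis genes -0.24, MYC and ribosome biogenesis genes 0.23, cholesterol genes 0.28, MHC class II genes 0.59 and ER chaperones 0.64. Only the replication and MHC class II calls of these 12 held by camera with an estimated correlation (adjusted p = 0.0173 each), and the MHC class II call is no sign of a separate response. Its genes other than CD74 stood at 0.219 FPKM at most in ANBL6BR DMSO, so their fall in ANBL6 fixed the direction. With log2(FPKM + 0.1) the medians of histones, interferon and glycolysis genes were -1.13, -0.99 and -0.42. Without ANBL6BR DMSO replicate 1 the medians of proteasome, NRF2, OXPHOS, BCL2 and cholesterol genes were -0.94, -1.12, -0.21, -0.16 and 0.51. Without ANBL6BR DMSO replicate 2 those of proteasome, NRF2, interferon, BCL2, MYC, cholesterol and ER chaperone genes were -0.33, -0.32, -0.6, -0.46, 0.13, 0.03 and 0.24. Calls were lost for BCL2 genes without ANBL6BR DMSO replicate 1, for cholesterol genes without ANBL6BR DMSO replicate 2 (camera adjusted p = 0.93), ANBL6 DMSO replicate 1 (0.0621) or ANBL6BR I3MO replicate 2 (0.0956), and for MYC genes without ANBL6 I3MO replicate 1 (0.211). Without ANBL6 I3MO replicate 1 the interferon median was -0.59, histones were -0.15 without ANBL6 DMSO replicate 1 and -0.27 without ANBL6 I3MO replicate 2, and MHC class II was 0.38 without ANBL6BR I3MO replicate 2.

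The ANBL6BR DMSO libraries differed across many gene lists. Median log2 differences, replicate 2 minus replicate 1, ran from -1.06 for plasma cell identity genes (1 of 18 higher) and -0.71 for ER chaperones (1 of 23) to 0.63 for proteasome subunits (33 of 33), 0.71 for NRF2 targets (19 of 21) and 0.88 for mitochondrial genes (13 of 13). HMOX1 was at 825 against 99 FPKM. Against a depth difference, the totals differed by 0.11 M fragments. Against an I3MO library under a wrong label, replicate 2 stood 1.11 above the ANBL6BR I3MO mean in replication genes. The 0.84 of proteasome genes restates the pattern. Stress from a proteasome inhibitor in that culture may explain part of this and was not decided by 2 lists outside the pattern: 16 of 17 heat shock genes were higher in replicate 2, but 11 of 27 ATF4 and CHOP targets. Other stresses stay open, and the labels name no difference between these libraries to test.

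Of 304 olfactory receptor genes that were at 0 in ARP1, RPMI8226 and U266, and not among the 15687 genes of the main tests, 22.7% (replicate 1) and 12.5% (replicate 2) were above 0 in the ANBL6 I3MO libraries, against at most 1.6% in the other 6 ANBL6 and ANBL6BR libraries. LincRNA genes (26.8% and 16.7%, against at most 2.8%) and processed pseudogenes (29.8% and 19.9%, against at most 5.8%) showed the same split. Greater depth is argued against by the totals, the larger of which was 0.37 M below the smaller DMSO total (-0.37). DNA carried into both libraries may explain genes of every class being touched, since even the lower value of 12.5% stood above the 1.6% elsewhere. A low-level effect of I3MO on ANBL6 was not tested and stays open, though the ANBL6BR libraries at the same dose stayed at or below 1.6%.

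IGLV2-14 held at most 4.0% of IGLV2 fragments in ANBL6 and at least 99.9% in ANBL6BR, in DMSO and I3MO alike. Sharing of fragments between IGLV2 paralogs would blur the split, and the smallest gap of 95.9 points argues against it. Some constant (IGLC) genes may not be counted. Of those counted, IGLC2 held 68.6% to 70.9% of 24551 to 34647 fragments in ANBL6. In ANBL6BR it held 0.9% to 1.3% of only 621 to 1522. Across genes, ANBL6 in DMSO correlated with ANBL6BR at r = 0.815 and with RPMI8226 at 0.831, where genes are not independent replicates. The names ANBL6 and ANBL6BR may therefore cover different clones or lines. In that case neither their 8123 differences in DMSO nor their 1328 differences in response are those of resistance alone. Selection of a minor clone during resistance, which would also give different clones, was not tested and stays open.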

How the results depend on the processing

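Median-ratio scaling, merged exon lengths, protein-coding genes only, the omission of ANBL6 from the joint test, and the alternatives for genes called in every model other than the fold threshold were chosen after seeing the data, as were other pseudocounts, scalings and left-out libraries for the lists and the test of other splits. Of 429 calls of named genes, 335 were kept with every single library left out and 94 were lost with at least 1. Calls lost were 2 with merged exon lengths, 5 with a minimum of 10 fragments, 16 with median-ratio scaling, 17 without a filter, 17 by limma-voom, 23 with a pseudocount of 0.1, 75 at an adjusted p under 0.01, 194 with a fold change of at least 2 required, 235 with only the libraries compared and 0 of 428 with protein-coding genes only, which takes fewer genes into the adjustment. The single reversal was CYP1A1 in the difference of responses, -0.58 by limma-voom against 0.38 (limma-voom adjusted p = 0.697), where ANBL6BR holds only traces of the gene. Without a filter 4181 genes were called in ANBL6 and 2888 in the difference of responses. With only the libraries compared, which leaves few degrees of freedom, the counts were 18 in ANBL6, 64 in ANBL6BR, 227 in ARP1, 974 in U266, 317 in the difference and 0 in every model. Requiring an absolute log2 fold change of at least 1 gave 118, 358, 947, 261 and 766 genes in ANBL6, ANBL6BR, ARP1, RPMI8226 and U266, 2931 in ANBL6BR against ANBL6, 314 in the difference, 2747 in the joint test and 1 in every model. At an adjusted p under 0.01 the counts were 413, 1528, 3783, 1227 and 2609 in the models, 373 in the difference, 3408 in the joint test and 27 in every model. With the replicate number as a replicate block they were 456 in ANBL6, 1541 in RPMI8226, 452 in the difference, 3942 in the joint test and 32 in every model. Across the models 2219 genes were called, in a fit of all 20 libraries blocked by model and replicate number. Libraries, and not models, were the replicates there. With the replicate block 61 calls of named genes were lost. Replicate numbers did not pair libraries (r of deviations between -0.11 and 0.1 across genes, which are not independent replicates). Limma-voom called 871 genes in the difference and 308 across the models, against 0 by limma. Across the models the count was 65 with protein-coding genes only, 3638 with all 20 libraries and the model as a block and 6659 as the mean of the 5 contrasts, which take the spread between libraries and not between models. It stayed 0 with each model left out in turn. The joint test called 5497 genes with the ANBL6 libraries left out.

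With single libraries left out, which assumes that the lone library of a group varies like the other groups, counts ranged from 355 to 1287 in ANBL6, 1418 to 3361 in ANBL6BR, 3509 to 5159 in ARP1, 1144 to 1427 in RPMI8226, 2869 to 4133 in U266, 6880 to 7638 in ANBL6BR against ANBL6, 555 to 2201 in the difference, 4898 to 8212 in the joint test, 0 to 1 across the models (1 without ANBL6BR DMSO replicate 1) and 36 to 138 in every model. Lists called ranged from 13 to 15 in ANBL6, 15 to 17 in ANBL6BR, 7 to 12 in ARP1, 11 to 13 in RPMI8226, 9 to 13 in U266, 10 to 12 in ANBL6BR against ANBL6, 12 to 17 in the difference and 13 to 15 across the models. With an estimated correlation 1, 2, 1, 1 and 3 lists were called in ANBL6, ANBL6BR, ARP1, RPMI8226 and U266, 2 in ANBL6BR against ANBL6, 2 in the difference and 0 across the models. By fry, which does not compare a list with other genes, 9 lists were called in ANBL6, 24 in ANBL6BR against ANBL6 and 0 across the models. Protein-coding genes alone left 5 lists called in ARP1. Where the construction of a setting does not show it, the cause was not tested. For the 0 genes called across the models by limma (2651 at an unadjusted p under 0.05), all 16 of 16 splits gave as many, the highest other being 0 (1185 at an unadjusted p under 0.05), and 16 splits are too few for a share under 0.05. Median-ratio scaling moved the median of all genes by at most 0.03, but this median holds many genes near 0. In ARP1 the scaling factors were 0.924 and 0.966 in DMSO and 1.144 and 1.105 with I3MO, and medians of lists went from 0.42 to 0.17 for ER chaperones, -0.27 to -0.51 for proteasome subunits, -0.18 to -0.41 for ribosomal proteins, -0.1 to -0.28 for NFkB targets and 0.56 to 0.31 for mitochondrial genes, whose call was lost (camera adjusted p = 0.104). With a pseudocount of 0.1 medians that moved by over 1.5 times all grew in the direction they had, such as MHC class II in ANBL6 from -0.39 to -0.86. Planned settings that need counts from the authors (other size factors, a count-based Wald test and filters on reads) were not run, since the files hold FPKM.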

Other observations

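The levels that follow were chosen after their values were seen. In DMSO, CCND1, which encodes cyclin D, stood at 130 and 137 FPKM in the U266 libraries, 26.0 and 25.8 in ANBL6 and at most 0.0476 in ANBL6BR, and with I3MO it was 21.3 and 25.9 in U266. MYCL, a relative of MYC, stood at 77.1 and 73.4 FPKM in U266 DMSO, where MYC was at 0.651 and 0.721, and at 37.0 in both U266 I3MO libraries. MYC was at 99.7 ± 6.88 FPKM in ANBL6 DMSO (SD, n = 2), 111 in both RPMI8226 DMSO libraries, and 10.9 and 2.55 in ANBL6BR DMSO. IGHE, the constant gene of immunoglobulin E, was at 628 and 669 FPKM in U266 DMSO and at most 0.345 in the DMSO libraries of the other models.

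MAF, a transcription factor gene of plasma cell tumours, was at 144 and 126 FPKM in RPMI8226 DMSO and 44.5 and 49.0 with I3MO, and at 88.4 and 80.7 in ANBL6 DMSO and 43.7 and 42.3 with I3MO. CDKN2C, which encodes an inhibitor of cyclin-dependent kinases, was at 50.1 and 45.1 FPKM in ANBL6BR DMSO and 33.5 and 31.4 in U266 DMSO, and with I3MO at 33.3 and 30.3 in ANBL6BR and 8.4 and 7.96 in U266. It was listed at 0 in all ARP1 and RPMI8226 libraries. HSPB1 went from 320 and 331 FPKM in ARP1 DMSO to 96.3 and 116 with I3MO. MALAT1, a nuclear long noncoding RNA, differed between replicates, with 3.45 and 21.2 FPKM in ANBL6BR DMSO and 18.2 and 2.09 in U266 I3MO.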
